A study of Homo sapiens with 27 samples.

How the data were processed

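The 3′ ends of poly(A)+ RNA were counted in 27 sequencing libraries of 3 human cell lines, H358, A549 and A549R, which the labels describe as lines of non-small cell lung cancer. The libraries fall into 9 groups of 3. H358 RNA came from whole cells treated with vehicle (DMSO), cisplatin or oxaliplatin. A549 and A549R RNA came from the cytosol after DMSO or cisplatin, and A549 RNA also from heavy polysomes, the fraction of messenger RNA that carries many ribosomes, after DMSO or cisplatin. Cisplatin and oxaliplatin, a pair of platinum compounds, were both given at 100 µM, and no time of exposure was used here. The series design text sets cisplatin-resistant against sensitive cells; A549R was read as the resistant counterpart of A549.

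Per the labels' protocols, poly(A)+ RNA was fragmented, reverse transcribed from an anchored oligo-dT primer and amplified by 16 cycles of PCR, fragments of 150 to 300 bases were selected, and single-end reads of 50 bases were made. The submitters' processing notes name Bowtie2 2.2.5, SAMtools 1.1 and bedtools 2.17.0, without saying what each was used for. Each library has its own deposited peak list, in which every peak has a position, a strand, a number and a whole-number read count. The authors deposited these counts without normalization, and the smallest count in every list was 5. The criteria by which the authors called and filtered peaks are not given in the sources used here. The processing notes name the mouse build mm9, but the lists hold a chromosome 22 and positions up to 249237867 on chromosome 1, 51239739 on chromosome 22 and 16571 on the mitochondrial genome, which fit the human build hg19. Positions are therefore given as in the lists, counted from 1, and read as hg19. No annotation or genome of that build was used here and the files do not pair peaks with gene names, so peaks are named by position alone, and whether a peak lies in an intron or a last exon is not stated.

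The lists were of 2 kinds. Peaks are numbered within each list with gaps, and 16 libraries listed 73.1% to 79.4% of their peak numbers, whereas the other 11 listed 30.7% to 42.3%. The 11 short lists were those of the 3 H358 oxaliplatin libraries, the 6 A549 cytosol libraries and the polysome libraries numbered 3 of both treatments. A total of 10484 merged peaks stood in every long list and in no short list, and 0 stood in every short list and in no long list. In the 9 short lists numbered by strand, skipped peak numbers were counted in the stretches where such peaks should lie. At least 99.8% of these stretches skipped as many numbers as there were such peaks, or more. Of the other stretches, at most 31.0% skipped any number. These peaks were thus called and then left out of the short lists, and a peak that a short list lacks is not a count of 0. The boundary between list kinds coincides with that between oxaliplatin and DMSO, between oxaliplatin and cisplatin, between A549R and A549, and, for 4 of the 6 polysome libraries, between polysomes and cytosol.

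Peaks of all libraries were merged where they overlapped by at least 1 base on a strand, which gave 233020 merged peaks, and a library's value was the sum of its own peaks in each. Before the data were examined, the design, the alternatives and the naming rule were fixed around intronic polyadenylation sites and last exons, with a test of each merged peak as the fallback should no annotation of the build be at hand. That fallback is called the all-peak test. It took merged peaks with a mean count of at least 5 over the libraries fitted together (47950 in H358, 57359 in cytosol, 74786 in polysomes and 59103 in polysomes and cytosol). The other peak sets were chosen after the data were examined. The kept class, 81800 peaks listed in at least 1 short list, was tried first, and its counts, block values and splits were seen; the naming rule then picked peaks that a whole group did not list. The measured peaks, those listed in every library of a fit, then took its place (14358 in H358, 16439 in cytosol, 21585 in polysomes and 17308 in polysomes and cytosol). That change raised the A549 cisplatin count from 481 to 1188, the polysome cisplatin count from 1 to 152 and the oxaliplatin count from 762 to 764, and lowered the count between A549R and A549 from 1323 to 345. Measured peaks leave out any peak that fell below listing in a single library, so complete losses are not among them. The 151220 peaks of no short list are called the unlisted class.

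In place of intronic site against last exon, a measured peak was compared with a stronger measured peak within 50 kb downstream on its strand, in a model with a term for each library; this is called an upstream pair, and pairs with the weaker peak downstream served as its mirror. Both peaks of a pair need not belong to 1 gene. With measured in place of kept-class pairs, the H358 cisplatin count went from 199 risen and 596 fallen to 300 and 252, and that between A549R and A549 from 120 and 328 to 11 and 8. Some peaks still followed the list kind: 1559 kept-class peaks with a mean count of at least 20 were at least 4 times higher in the long than in the short polysome lists, of which 146 were among the measured peaks of H358, 148 of cytosol, 265 of polysomes and 146 of polysomes and cytosol. They were not named in comparisons that cross list kinds, and counts without them were added. Regions were tested as windows of 5 Mb with at least 20 members, each member the strongest measured peak within 50 kb.

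Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 after TMM scaling, two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. The H358 libraries were fitted together, as were the 12 cytosol libraries, the 6 polysome libraries, and the 12 A549 libraries of both fractions. Windows were tested with camera of limma 3.58.1 at a preset correlation of 0.01, which does not use the spread between libraries of a group as a test per peak does, and again with the correlation estimated. Single values per library were compared by exact two-sided permutation tests, in which 3 libraries against 3 cannot give a p below 0.1. Where replicate numbers pair the libraries, exact sign flips over same-numbered pairs were added after the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest. Normalised counts (CPM) are counts scaled to a common total over the measured peaks of a fit, after TMM scaling. Levels from separate fits are therefore not on the same scale. Log2 changes are printed with their standard error.

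Alternatives fixed beforehand were DESeq2 1.42.0, RLE scaling, no count minimum, replicate number as a block, merging of peaks within 100 bases, libraries thinned to the smallest total of the fit, and omission of each library in turn. Replicate numbers were taken to pair the libraries where the deviations of same-numbered libraries from their group means correlated above 0.1 over measured peaks in every pair. This held for oxaliplatin against DMSO (lowest 0.15), cisplatin in A549 cytosol (0.332), A549R cytosol (0.177) and polysomes (0.486), and A549R against A549 (0.125). It also held for polysomes against cytosol and the difference between their responses (0.184 in both). It did not for cisplatin in H358 (0.035), cisplatin against oxaliplatin (-0.097) and the difference between the A549R and A549 responses (-0.01). The labels state no such pairing. For oxaliplatin against DMSO and between polysome and cytosol groups, 2 of 3 libraries correlated best with their own number. In the other comparisons that passed, 3 of 3 did. In polysomes both libraries numbered 3 had short lists and the others long lists, and depth also followed the number. Same-numbered polysome libraries could thus deviate together without being paired samples. The check was made after block counts of the kept class had been seen, over which oxaliplatin and A549R against A549 did not pass. Named peaks were those with the largest changes among calls with a mean count of at least 20 and no overlap between the groups' libraries, by the rule fixed beforehand; the few largest are printed.

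The tests were tried on simulated counts with known changes. Over measured peaks, 4-fold changes were recovered for 88% of peaks in the H358 cisplatin comparison, 87% in A549 cytosol, 64% in polysomes and 97% between polysomes and cytosol, and 2-fold changes for 25%, 22%, 5% and 60%. Over all peaks at most 1% of 4-fold changes were recovered in these comparisons; the cause was not tested. For peaks relative to a neighbour, 4-fold changes were recovered for 80.4%, 82.3%, 23.7% and 97.9%. Replicates of each group differed by more than counting noise (chi-square per peak 5.56 to 54.7).

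The libraries held 3024814 to 11997535 counts in listed peaks. PCR reads without molecular identifiers are not independent molecules, so counting intervals cover counting error only. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Tests of gene lists, of intronic sites against last exons and of gene length were not analysed here, as they need an annotation. Peaks on chromosome Y were left out of naming, windows and plots.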

Results

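RNA 3′ ends were counted by 3′-seq in H358, A549 and A549R cells, lines of non-small cell lung cancer, to ask how transcript ends change with cisplatin and how resistant differ from sensitive cells. Each of the 9 groups held 3 libraries. Total counts per library ran from 5248796 to 9058438 in H358 DMSO, 3765404 to 6542394 in H358 cisplatin and 4921873 to 6036451 in H358 oxaliplatin. In cytosol they ran from 3372128 to 5377638 in A549 DMSO, 3739215 to 5484796 in A549 cisplatin, 3024814 to 7564772 in A549R DMSO and 6171900 to 7222039 in A549R cisplatin. In heavy polysomes they ran from 3609493 to 11997535 in DMSO and 5204042 to 11687036 in cisplatin. Each peak below is named by its position in hg19, which the lists fit, and its strand.

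**Figure D1:**
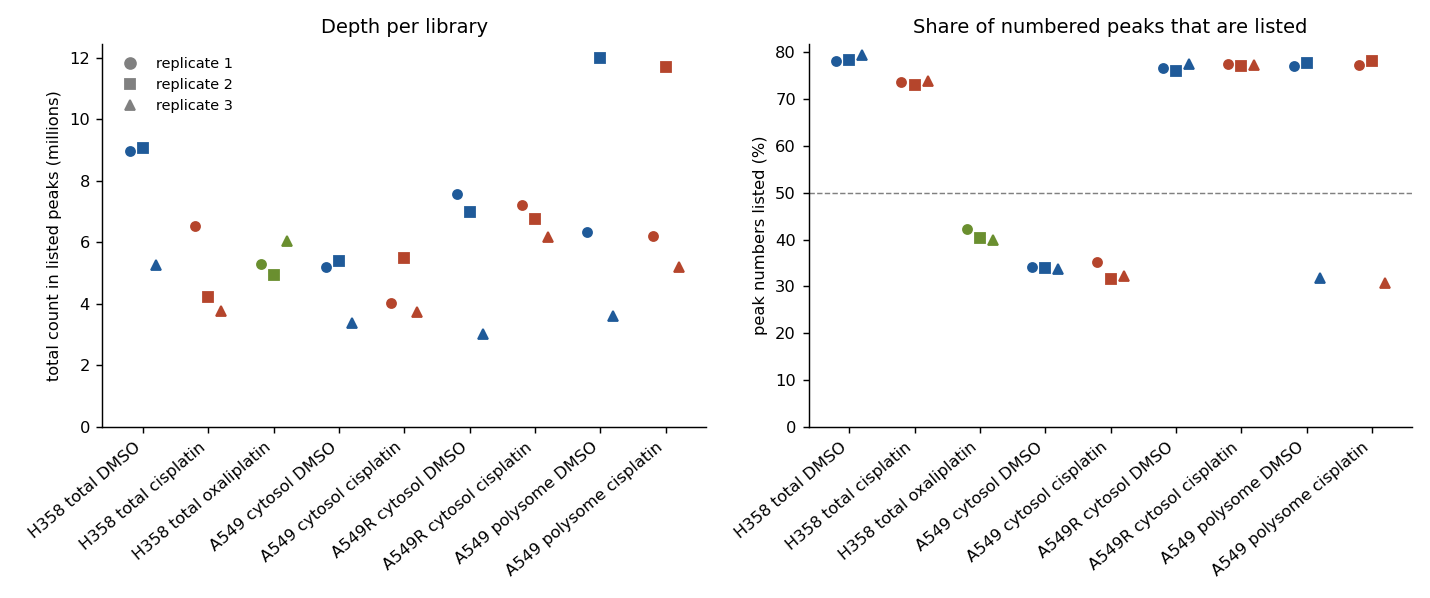
Total count in listed peaks (left) and share of peak numbers that each list holds (right, percent) for each library, with blue for DMSO, red for cisplatin, green for oxaliplatin and the marker for the replicate number. Totals ran from 3024814 to 11997535, and 11 lists held 30.7% to 42.3% of their numbers against 73.1% to 79.4% for the other 16.

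The first question was how cisplatin changes transcript ends in H358 cells. After cisplatin, 1695 of 14358 measured peaks rose and 2066 fell. The steepest rise was at chromosome 1, 155277610 to 155278203, minus strand, from 48.7 ± 3.48 to 2391 ± 678 CPM (n = 3; log2 change 5.62 ± 0.28 SE, adjusted p 3.68e-11, edgeR). Next came chromosome 20, 26189768 to 26190303, minus strand, from 5.50 ± 1.56 to 273.6 ± 119 CPM (log2 5.61 ± 0.53). The steepest fall was at chromosome 6, 43966601 to 43967301, plus strand, from 598 ± 145 to 10.4 ± 4.89 CPM (log2 -5.81 ± 0.38, adjusted p 5.5e-10, edgeR). Next came chromosome 16, 81744519 to 81745373, plus strand, from 118.5 ± 48.5 to 8.88 ± 1.74 CPM (log2 -3.74 ± 0.36). The mitochondrial genome took 9.11 ± 0.23% of kept-class counts in DMSO and 21.9 ± 1.76% in cisplatin, higher in 3 of 3 libraries (2.41-fold, exact permutation p 0.1, the smallest that 3 against 3 allow; adjusted p 0.183 over 11 such tests). The unlisted class took 18.1 ± 0.40% of all counts in DMSO and 29.5 ± 3.36% in cisplatin, again higher in 3 of 3 (exact p 0.1, adjusted 0.183).

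Transcript ends also shifted relative to their neighbours. Of 4432 upstream pairs, the upstream peak rose against the stronger downstream peak in 300 and fell in 252, with a median change of 0.01 on the log2 scale. Of 2294 pairs with the weaker peak downstream, it rose in 283 and fell in 209. The largest rise was that of chromosome 19, 7563981 to 7564043, plus strand, which went from 3.67 ± 1.99% to 73.0 ± 5.07% of the counts of its pair, whose stronger peak lay 21720 bases downstream (log2 6.10 ± 0.40, adjusted p 1.63e-07, edgeR). That at chromosome 17, 79892806 to 79894400, minus strand, went from 0.95 ± 0.54% to 24.2 ± 6.38% over 47760 bases (log2 5.16 ± 0.41). Among falls, chromosome 14, 73425921 to 73426370, plus strand, went from 73.0 ± 7.67% to 8.28 ± 1.39% over 3882 bases (log2 -4.82 ± 0.38). Chromosome 20, 34817275 to 34818351, plus strand, went from 60.7 ± 2.64% to 7.42 ± 2.51% over 26832 bases (log2 -4.17 ± 0.37). With neighbours sought within 20 kb only, 310 pairs changed.

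The measured set of H358 also requires listing in the oxaliplatin libraries, so all its peaks are of the kept class. Among peaks listed in every DMSO and cisplatin library, 5043 rose and 5006 fell. The unlisted class held 4134 of these rises and 210 of the falls, and the kept class 909 and 4796. The near balance of rises and falls among measured peaks thus depends on scaling that set alone. Over all peaks, 2543 rose and 6433 fell, and with RLE scaling 5542 rose and 3890 fell; without replicate 1 of H358 DMSO the all-peak count was 5559 in place of 8976, with DESeq2 16047 and without a count minimum 14402.

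**Figure D2:**
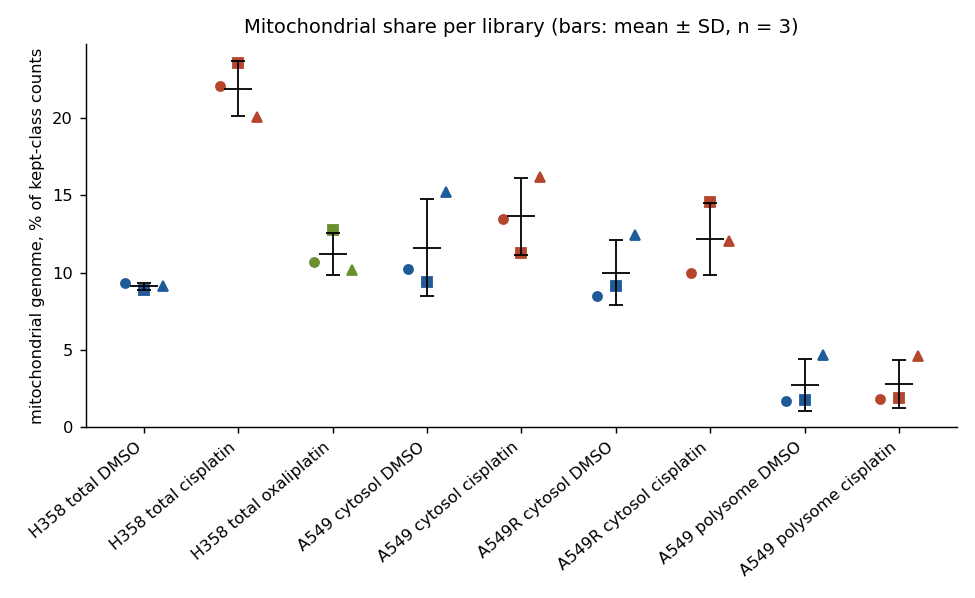
Share of kept-class counts in mitochondrial peaks (percent) for each library, with blue for DMSO, red for cisplatin, green for oxaliplatin, the marker for the replicate number (circle, 1; square, 2; triangle, 3) and bars for mean ± SD of 3 libraries. The H358 cisplatin libraries lay between 20.1% and 23.6%, above the H358 DMSO libraries at 8.89% to 9.35%, and the polysome libraries lay between 1.70% and 4.67%.

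Oxaliplatin was compared with DMSO in the same H358 experiment. Among measured peaks 182 rose and 582 fell. The steepest rise was at chromosome 19, 55896660 to 55897206, minus strand, from 1.06 ± 0.20 to 6.48 ± 0.67 CPM (n = 3; log2 2.62 ± 0.38, adjusted p 0.000137, edgeR). Another was at chromosome 1, 209849218 to 209849741, plus strand, from 3.38 ± 0.17 to 19.4 ± 5.75 CPM (log2 2.52 ± 0.35). The peak at 43966601 on chromosome 6 fell here too, from 598 ± 145 to 5.91 ± 2.67 CPM (log2 -6.67 ± 0.39, adjusted p 7.34e-11, edgeR). Next came chromosome 20, 2446011 to 2446478, minus strand, from 88.8 ± 13.8 to 3.73 ± 0.86 CPM (log2 -4.55 ± 0.30). Of the upstream pairs 72 rose and 103 fell. The share of chromosome 17, 57917126 to 57917958, plus strand, went from 36.3 ± 2.78% to 85.8 ± 0.43% of its pair over 1630 bases (log2 3.40 ± 0.28). That of chromosome 9, 123666226 to 123666660, minus strand, went from 12.9 ± 4.49% to 50.7 ± 13.4% over 48288 bases (log2 2.95 ± 0.40). The peak at 2446011 on chromosome 20 went from 13.8 ± 2.26% to 0.74 ± 0.08% over 3864 bases (log2 -4.39 ± 0.29), and chromosome 4, 1717620 to 1718065, minus strand, from 33.2 ± 9.91% to 4.604 ± 1.41% over 23054 bases (log2 -3.34 ± 0.34). Per library, the median log2 ratio of weaker to stronger peak over upstream pairs was -2.94 ± 0.08 with oxaliplatin and -2.76 ± 0.03 with DMSO, a difference of -0.18, lower in 3 of 3 libraries (exact permutation p 0.1, adjusted 0.35; exact sign-flip p 0.25). The mitochondrial share was 11.2 ± 1.39%, above DMSO in 3 of 3 libraries (1.23-fold, exact permutation p 0.1, adjusted 0.183, and exact sign-flip p 0.25 over 3 pairs). Oxaliplatin lists were short and DMSO lists long. In A549 polysome DMSO the short list had a share of 4.67% and the long lists 1.70% and 1.77%, so this rise cannot be told apart from list kind.

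Replicate numbers were taken to pair these libraries by the correlation rule, though the labels state no pairing. With the numbers as a block 2236 measured peaks (858 risen, 1378 fallen) and 361 upstream pairs changed. The measured count fell from 764 to 332 without replicate 1 of DMSO, 323 without replicate 2 and 340 without replicate 3 of oxaliplatin, and the pair count from 175 to 74, 77 and 69. Over all peaks 68 rises and 22482 falls were called, and 74.3% of calls were at peaks that a whole group did not list. Without measured peaks that follow the list kind, which differs between these groups, 179 rose and 538 fell.

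The difference between the platinum compounds at 100 µM was tested directly. Among measured peaks 1398 were higher with cisplatin than with oxaliplatin and 1356 were lower; without peaks that follow the list kind, which differs between these groups, 1351 and 1328. The largest difference upward was at chromosome 20, 26188996 to 26189627, minus strand, with 229 ± 128 CPM for cisplatin against 2.55 ± 1.20 for oxaliplatin (n = 3; log2 6.49 ± 0.53, adjusted p 1.49e-08, edgeR). The peak at 2446011 on chromosome 20 had 275.6 ± 76.4 against 3.73 ± 0.86 CPM (log2 6.18 ± 0.32). It rose with cisplatin (log2 1.63 ± 0.25) and fell with oxaliplatin. The largest downward was at chromosome 5, 159399611 to 159400027, plus strand, with 4.04 ± 1.20 against 38.0 ± 8.67 CPM (log2 -3.19 ± 0.36, adjusted p 1.46e-06, edgeR). Next came chromosome 8, 118811597 to 118812143, minus strand, with 5.36 ± 1.85 against 48.0 ± 12.0 CPM (log2 -3.11 ± 0.32). As a share of its pair, the peak at 2446011 on chromosome 20 took 38.6 ± 5.59% with cisplatin and 0.74 ± 0.08% with oxaliplatin (log2 6.37 ± 0.29). The peak at 79892806 on chromosome 17 took 24.2 ± 6.38% and 0.59 ± 0.30% (log2 5.68 ± 0.42). In the other direction, chromosome 14, 35009857 to 35010002, plus strand, took 8.94 ± 5.00% and 68.0 ± 3.26% (log2 -4.56 ± 0.43), and the peak at 73425921 on chromosome 14 took 8.28 ± 1.39% and 64.5 ± 6.70% (log2 -4.31 ± 0.36). The mitochondrial share was 1.96-fold higher with cisplatin, in 3 of 3 libraries (exact permutation p 0.1, adjusted 0.183). This share too was compared across list kinds. The 95% interval of a difference, not adjusted for the number of peaks, reached a median of 0.82 to either side on the log2 scale. Calls needed an adjusted p, so a peak that was not called may differ by more than that. The all-peak count, 19731 higher and 3334 lower, fell to 1780 and 3225 over the kept class, and 83.4% of its calls were at peaks that a whole group did not list.

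In A549 cytosol, cisplatin raised 541 and lowered 647 of 16439 measured peaks. The peak at chromosome 1, 203278289 to 203278767, plus strand, rose from 3.63 ± 0.86 to 48.8 ± 10.1 CPM (n = 3; log2 3.71 ± 0.44, adjusted p 0.000476, edgeR). That at chromosome 6, 36653514 to 36655201, plus strand, rose from 112 ± 29.4 to 1297 ± 315 CPM (log2 3.54 ± 0.54). The peak at chromosome 3, 17201779 to 17202123, minus strand, fell from 22.8 ± 0.29 to 2.18 ± 0.66 CPM (log2 -3.41 ± 0.35, adjusted p 0.000155, edgeR). That at chromosome 7, 133750158 to 133750521, plus strand, fell from 37.5 ± 5.00 to 3.63 ± 1.94 CPM (log2 -3.37 ± 0.33). Of 4797 upstream pairs 63 rose and 87 fell, and of 2994 pairs with the weaker peak downstream 64 rose and 64 fell. Chromosome 11, 65180713 to 65181047, plus strand, went from 4.599 ± 0.64% to 36.9 ± 19.04% of its pair over 12056 bases (log2 3.46 ± 0.62). Chromosome 1, 949363 to 949995, plus strand, went from 12.8 ± 4.43% to 55.1 ± 16.2% over 41586 bases (log2 3.16 ± 0.44). Falls were led by chromosome 1, 910185 to 910614, plus strand, which went from 51.1 ± 13.2% to 10.1 ± 8.96% over 39280 bases (log2 -3.68 ± 0.70). Its partner is the peak at 949363, which itself rose (log2 3.50 ± 0.60), so this fall and that rise are not separate changes. Chromosome 16, 30930003 to 30930483, minus strand, went from 54.1 ± 8.58% to 11.3 ± 7.82% over 31029 bases (log2 -3.33 ± 0.50). The mitochondrial share was 11.6 ± 3.17% and 13.7 ± 2.49% (exact permutation p 0.4); between same-numbered libraries it was higher with cisplatin in 3 of 3 pairs (exact sign-flip p 0.25, the smallest that 3 pairs allow).

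With the paired replicate numbers as a block 1959 measured peaks changed (889 risen, 1070 fallen), and 63 upstream pairs changed within 20 kb. The measured count fell from 1188 to 638 and 422 without replicates 1 and 2 of A549 DMSO, and to 407 and 432 without replicates 2 and 3 of A549 cisplatin; the pair count fell from 150 to 68, 34, 51 and 40. Over all peaks 180 rises and 147 falls were called, with the block 144 changes, with DESeq2 2470 and without a count minimum 3441. Its count of 327 became 49, 55 and 112 without A549 DMSO replicates 1, 2 and 3, 119 and 60 without A549 cisplatin replicates 2 and 3, 152, 163 and 517 without A549R DMSO replicates 1, 2 and 3, and 147 without A549R cisplatin replicate 1.

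In A549R cytosol, 402 measured peaks rose with cisplatin and 345 fell. The peak at 203278289 on chromosome 1 again led the rises, from 3.59 ± 1.57 to 53.04 ± 30.1 CPM (n = 3; log2 3.95 ± 0.47, adjusted p 0.000558, edgeR). Next came chromosome 14, 105945928 to 105946552, plus strand, from 9.40 ± 1.94 to 89.2 ± 23.8 CPM (log2 3.24 ± 0.78). The steepest fall was at chromosome 17, 9153691 to 9153965, minus strand, from 32.0 ± 10.6 to 3.52 ± 2.50 CPM (log2 -3.20 ± 0.50, adjusted p 0.00318, edgeR). The peak at 133750158 on chromosome 7 fell from 23.9 ± 2.81 to 2.81 ± 0.87 CPM (log2 -3.09 ± 0.35). Of the upstream pairs 47 rose and 59 fell, led by the peak at 65180713 on chromosome 11, which went from 17.003 ± 8.95% to 58.2 ± 21.8% of its pair (log2 3.02 ± 0.65). The peak at 105945928 on chromosome 14 went from 1.40 ± 0.24% to 8.76 ± 0.86% over 8728 bases (log2 2.76 ± 0.31). Among falls, chromosome 1, 36805220 to 36805642, minus strand, went from 61.1 ± 4.92% to 11.7 ± 4.30% over 17531 bases (log2 -3.62 ± 0.69), and the peak at 910185 on chromosome 1 from 48.1 ± 15.6% to 8.95 ± 4.71% (log2 -3.23 ± 0.66); the partner of the latter, at 949363, itself rose (log2 2.71 ± 0.58). The mitochondrial share was 10.0 ± 2.12% in DMSO and 12.2 ± 2.33% in cisplatin (exact permutation p 0.3; higher in 2 of 3 pairs, exact sign-flip p 0.5).

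With the replicate block 1552 measured peaks changed (799 risen, 753 fallen), and over peaks listed in every A549R library, fitted alone, 400; 32 upstream pairs changed within 20 kb. The measured count of 747 became 193 and 244 without A549R DMSO replicates 1 and 2, and 237, 201 and 1243 without A549R cisplatin replicates 1, 2 and 3. The pair count of 106 became 21, 20, 15 and 24 without A549R DMSO replicates 1 and 2 and cisplatin replicates 1 and 2, and 70 without A549 cisplatin replicate 2. Over all peaks 155 rises and 74 falls were called, with the block 79 changes, with DESeq2 1937 and without a count minimum 3357. Its count of 229 became 100, 94 and 95 without A549 DMSO replicates 1 and 2 and A549 cisplatin replicate 2, 40 and 99 without A549R DMSO replicates 1 and 2, and 16, 43 and 405 without A549R cisplatin replicates 1, 2 and 3.

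The cisplatin responses of A549R and A549 were then tested against each other. Over measured peaks edgeR called 0 differences, with 307 of 16439 peaks at an unadjusted p under 0.05, and DESeq2 called 0 with 310. That is a smaller share than the 0.05 that would come without any difference. The test may thus be too strict, and its 0 calls do not show equal responses. The peak at 203278289 on chromosome 1 had log2 changes of 3.95 ± 0.47 in A549R and 3.71 ± 0.44 in A549, and that at 36653514 on chromosome 6 had 3.16 ± 0.53 and 3.54 ± 0.54. The 95% interval of the difference, not adjusted for the number of peaks, reached a median of 0.97 to either side. Calls needed an adjusted p, so differences larger than that could go uncalled. Without replicate 3 of A549 DMSO or replicate 3 of A549R cisplatin 1 difference was called. The all-peak test called 7 (3 higher in A549R, 4 lower), all at peaks that a whole group did not list, and DESeq2 called 125; without a count minimum edgeR called 1060. The count of 7 became 12, 15, 11, 15, 24 and 13 without A549 DMSO replicate 1, A549 cisplatin replicate 1, A549R DMSO replicate 1, A549 cisplatin replicate 2, A549 DMSO replicate 3 and A549 cisplatin replicate 3.

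**Figure D3:**
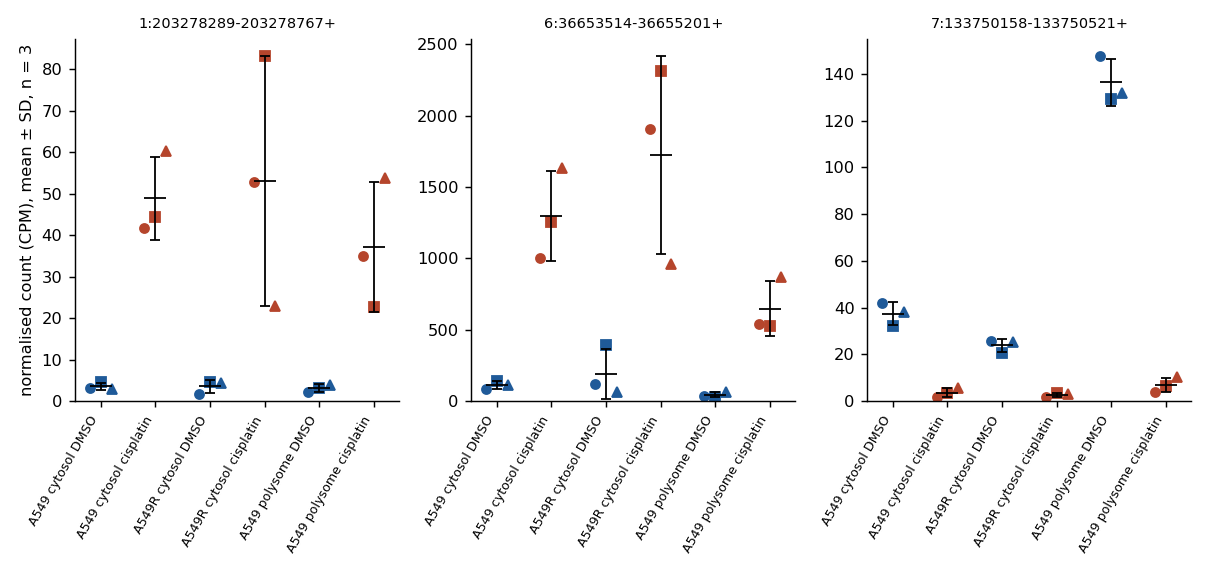
Normalised count (CPM) of 3 named peaks in the A549 and A549R libraries, with blue for DMSO, red for cisplatin, the marker for the replicate number (circle, 1; square, 2; triangle, 3) and bars for mean ± SD of 3 libraries. The peak on chromosome 6 stood at 112 ± 29.4 CPM in A549 DMSO cytosol and 1297 ± 315 CPM after cisplatin, and that on chromosome 7 went from 37.5 ± 5.00 to 3.63 ± 1.94 CPM. Cytosol and polysome values come from separate fits, so their levels are not on the same scale.

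Resistant and sensitive cells were compared in DMSO. Whole regions differed between the lines: of 110 windows of 5 Mb holding 3194 measured members, 13 were higher in A549R and 15 lower, and in cisplatin 14 and 14. With the correlation estimated in place of preset, 8 windows passed in DMSO and 11 in cisplatin, and the 8, which passed in both, lay on chromosomes 22 (3), 19 (2), 7 (2) and 16 (1). The 4 windows tested on chromosome 22 between 20 and 45 Mb were all higher in A549R, with median log2 differences of 0.32 to 0.51 in DMSO and 0.46 to 0.61 in cisplatin over 119 members. On chromosome 19, 6 of 10 windows, between 30 and 60 Mb, were lower (-0.48 to -0.23, 195 members), as were 2 of 6 on chromosome 7 between 95 and 105 Mb (-0.56 to -0.46). On chromosome 6 between 30 and 45 Mb, 3 of 3 windows were higher (0.29 to 0.39), and on chromosome 9 between 100 and 140 Mb, 3 of 5 were (0.29 to 0.53). Of these windows on chromosomes 6 and 9, 0 passed with the correlation estimated. In DMSO and cisplatin alike, 25 windows on 9 chromosomes passed in the same direction, 13 higher and 12 lower, where 1.66 and 1.91 would be shared by independent sets. Both comparisons set the same lines and list kinds against each other, in the same fit and over the same members. The sets are therefore not independent, and these expected numbers are no measure of chance. Other splits of the 6 DMSO libraries called up to 26 windows, so the number of windows alone does not set the lines apart.

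**Figure D4:**
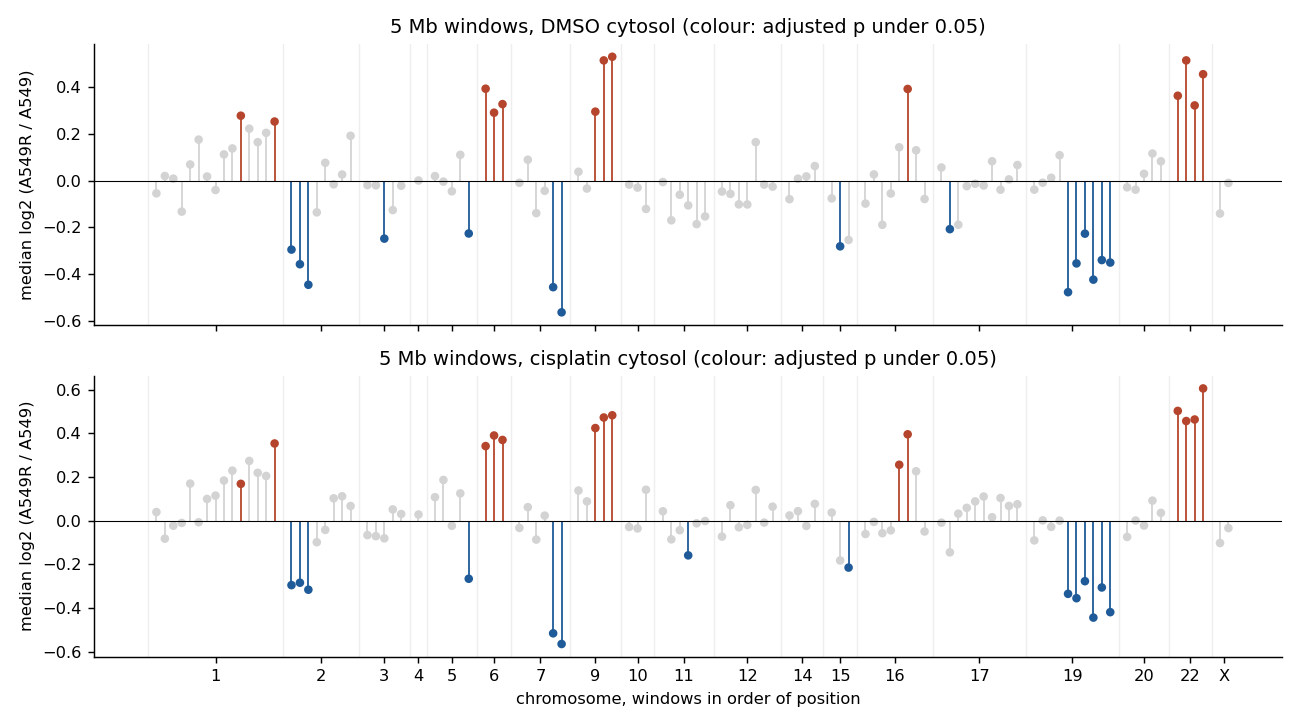
Median log2 difference between A549R and A549 over the measured members of each 5 Mb window, in order of position, in DMSO (top) and cisplatin (bottom), with red for windows higher and blue for windows lower in A549R at an adjusted p under 0.05 (camera) and grey for the others. The 4 windows of chromosome 22 stood at 0.32 to 0.51 in DMSO, and 6 windows of chromosome 19 stood at -0.48 to -0.23.

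Among single measured peaks, 180 were higher in A549R and 165 lower. The largest difference upward was at chromosome 14, 80667890 to 80669337, minus strand, with 100.2 ± 37.4 CPM in A549R against 4.65 ± 3.95 in A549 (n = 3; log2 4.55 ± 0.47, adjusted p 5.22e-05, edgeR). Next came chromosome 12, 50570647 to 50571859, minus strand, with 47.2 ± 27.4 against 3.65 ± 2.35 CPM (log2 3.65 ± 0.53). The largest downward was at chromosome 22, 24584844 to 24585083, plus strand, with 2.11 ± 1.46 against 43.9 ± 20.8 CPM (log2 -4.62 ± 0.51, adjusted p 0.000102, edgeR). Next came chromosome 19, 49102392 to 49102691, plus strand, with 6.09 ± 4.26 against 80.7 ± 25.1 CPM (log2 -3.91 ± 0.63). Upstream pairs differed in 19 places, 11 with the upstream peak higher in A549R and 8 with it lower. Chromosome 22, 24574242 to 24574661, plus strand, took 84.0 ± 7.77% of its pair in A549R and 17.1 ± 4.57% in A549 (log2 4.83 ± 0.40). Its partner, 10512 bases downstream, is the peak at 24584844 named above. The peak at 2446011 on chromosome 20 took 5.89 ± 1.08% against 1.46 ± 0.11% (log2 2.07 ± 0.25). Lower shares in A549R were those of chromosome 7, 156956495 to 156956560, plus strand, with 6.74 ± 3.23% against 61.2 ± 19.9% over 28772 bases (log2 -4.41 ± 0.72), whose partner was itself higher in A549R (3.42 ± 0.61), and of chromosome 15, 41849132 to 41849381, plus strand, with 31.1 ± 6.995% against 70.0 ± 4.69% over 408 bases (log2 -2.29 ± 0.36). Mitochondrial peaks took 10.0 ± 2.12% in A549R and 11.6 ± 3.17% in A549 (exact permutation p 0.5), and were lower in A549R in 3 of 3 same-numbered pairs (exact sign-flip p 0.25). This share too was compared across list kinds.

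The windows were chosen after the data were examined. Lines and list kinds coincided here: 39 of the 180 higher peaks followed the list kind, and without such peaks 141 were higher and 164 lower. With the paired replicate numbers as a block 916 measured peaks (442 higher, 474 lower) and 54 pairs differed, and over peaks listed in the 6 DMSO libraries, fitted alone, 224 peaks. The measured count of 345 became 131, 131 and 534 without A549 DMSO replicates 1, 2 and 3 and 137 and 130 without A549R DMSO replicates 1 and 2, and the pair count of 19 became 10 and 38 without A549 DMSO replicates 2 and 3 and 9 without A549R DMSO replicate 1 or 2. Over all peaks 24968 were higher and 1842 lower, and 92.8% of calls were at peaks that a whole group did not list.

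Cisplatin was next compared with DMSO in RNA from A549 heavy polysomes. Of 21585 measured peaks 91 rose and 61 fell. The peak at 36653514 on chromosome 6 rose from 45.1 ± 18.8 to 646.6 ± 193 CPM (n = 3; log2 3.84 ± 0.35, adjusted p 0.00349, edgeR). That at 949363 on chromosome 1 rose from 5.70 ± 1.14 to 80.1 ± 74.7 CPM (log2 3.80 ± 0.63). The peak at 133750158 on chromosome 7 fell from 136.3 ± 9.90 to 6.87 ± 3.13 CPM (log2 -4.28 ± 0.34, adjusted p 0.00329, edgeR). Chromosome 7, 1855423 to 1855751, minus strand, fell from 36.4 ± 1.22 to 2.19 ± 0.88 CPM (log2 -4.05 ± 0.35). Of 7687 upstream pairs 10 rose and 7 fell. The peak at 65180713 on chromosome 11 went from 19.3 ± 2.67% to 76.1 ± 10.6% of its pair (log2 3.81 ± 0.46), and that at 949363 on chromosome 1 from 3.41 ± 0.75% to 26.7 ± 16.6% (log2 3.23 ± 0.55). Chromosome 1, 910995 to 911269, plus strand, went from 55.8 ± 6.45% to 10.97 ± 5.87% over 38547 bases (log2 -3.52 ± 0.53); its partner was the risen peak at 949363, and with neighbours within 20 kb it had another partner and a log2 change of 0.36. Chromosome 11, 4113715 to 4114023, plus strand, went from 5.01 ± 0.60% to 1.14 ± 0.55% over 45966 bases (log2 -2.26 ± 0.38). The mitochondrial share was 2.71 ± 1.69% in DMSO and 2.75 ± 1.56% in cisplatin (exact permutation p 0.7; higher in 2 of 3 pairs, exact sign-flip p 0.5).

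With the paired replicate numbers as a block 2031 measured peaks (949 risen, 1082 fallen) and 229 pairs changed, and DESeq2 called 1562 peaks. The measured count of 152 became 20, 32, 11 and 42 without DMSO replicate 1, cisplatin replicate 1, DMSO replicate 2 and cisplatin replicate 2. Without both libraries numbered 3, which had short lists, it was 168. Peaks for that count were drawn anew from those listed in the remaining libraries, so 168 and 152 do not cover the same peaks. The pair count of 17 became 0, 0, 0, 2, 7 and 10 without DMSO replicate 1, cisplatin replicate 1, DMSO replicate 2, cisplatin replicate 2, DMSO replicate 3 and cisplatin replicate 3, and 3 within 20 kb. Over all peaks edgeR called 0, with 1166 of 74786 at an unadjusted p under 0.05, and DESeq2 called 375. The 1166 are a smaller share than would come without any change.

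Polysome RNA was compared with cytosol RNA in A549 over both treatments. Of 5527 upstream pairs, the upstream peak was lower on polysomes against its downstream neighbour in 1001 and higher in 587, with a median log2 difference of -0.24. Of 3215 pairs with the weaker peak downstream, 536 were lower and 504 higher (median 0.07). Per library, the median log2 ratio of weaker to stronger peak over upstream pairs was -2.66 ± 0.06 on polysomes and -2.48 ± 0.06 in cytosol (n = 6), with each polysome library below each cytosol library (exact permutation p 0.00216, adjusted 0.0302 over 14 such tests). That test ignores the pairing by number. Exact sign flips over 6 pairs, all of them lower on polysomes, gave p 0.0312, the smallest possible, and 0.438 adjusted over 14 tests. Even the smallest possible p could not pass that adjustment, so the paired test decides nothing. With both treatments of a number flipped together the exact p was 0.25, the smallest that 3 numbers allow. The difference of -0.18 was no larger than that of oxaliplatin from DMSO in H358, where the list kinds differ. The latter did not pass, which 3 libraries against 3 cannot do. Over the mirror pairs it was -1.93 ± 0.06 in both (exact p 0.959). The share of chromosome 17, 4608088 to 4608506, minus strand, was 2.52 ± 0.70% of its pair on polysomes and 29.7 ± 7.75% in cytosol, over 32866 bases (log2 -4.01 ± 0.24). That of chromosome 22, 50961991 to 50962338, minus strand, was 1.71 ± 0.62% and 18.9 ± 5.11% over 20529 bases (log2 -3.71 ± 0.30). In the other direction, chromosome 19, 5668195 to 5668496, plus strand, took 11.1 ± 2.51% and 0.74 ± 0.20% over 23286 bases (log2 4.06 ± 0.19). Chromosome 11, 118914892 to 118915377, minus strand, took 33.3 ± 6.61% and 3.24 ± 0.88% over 28678 bases (log2 3.90 ± 0.18).

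**Figure D5:**
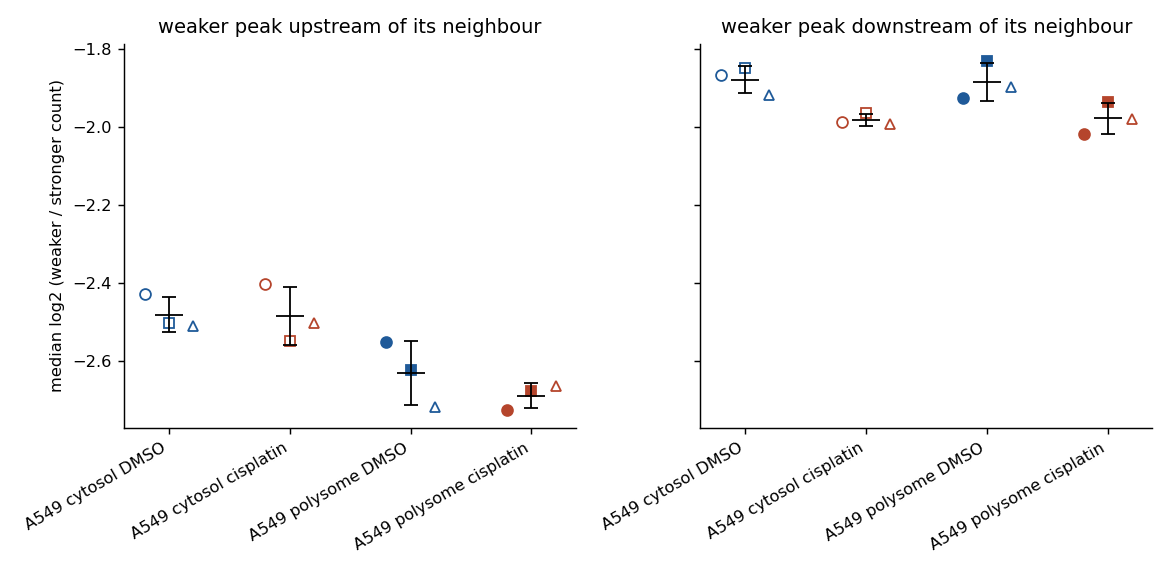
Median log2 ratio of the weaker to the stronger peak of a pair in each A549 library, for pairs with the weaker peak upstream (left) and downstream (right), with blue for DMSO, red for cisplatin, open markers for short and filled markers for long peak lists, the marker for the replicate number (circle, 1; square, 2; triangle, 3) and bars for mean ± SD of 3 libraries. Over upstream pairs the 6 polysome libraries lay between -2.73 and -2.55 and the 6 cytosol libraries between -2.55 and -2.40, without overlap.

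Among 17308 measured peaks 5070 were higher on polysomes and 5065 lower. The largest difference upward was at chromosome 9, 131095295 to 131095316, plus strand, with 42.5 ± 14.3 CPM on polysomes against 3.53 ± 1.19 in cytosol (n = 6; log2 3.61 ± 0.29, adjusted p 4.81e-07, edgeR). Next came chromosome 2, 8890331 to 8890357, plus strand, with 29.5 ± 4.53 against 3.37 ± 1.36 CPM (log2 3.17 ± 0.25). The largest downward was at chromosome 20, 55933895 to 55934365, minus strand, with 7.71 ± 3.25 against 137.4 ± 35.6 CPM (log2 -4.15 ± 0.22, adjusted p 3.92e-08, edgeR). Next came chromosome 19, 50642375 to 50642499, minus strand, with 4.48 ± 2.36 against 75.3 ± 39.7 CPM (log2 -4.06 ± 0.39). The mitochondrial share was 2.73 ± 1.46% on polysomes and 12.6 ± 2.78% in cytosol, lower in 6 of 6 libraries (exact permutation p 0.00216, the smallest that 6 against 6 allow; adjusted 0.0238). Exact sign flips gave p 0.0312 over 6 pairs (adjusted 0.172) and 0.25 over 3 numbers, the smallest possible in each. Neither could pass once adjusted, so the paired tests decide nothing for this difference. The polysome libraries with short lists had the highest shares among polysomes, 4.67% and 4.56%, against 1.70% to 1.89% in the other 4. With neighbours within 20 kb, 268 upstream pairs were higher and 576 lower.

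By their identifiers the fractions came from separate library sets, and 4 polysome lists were long while all 6 A549 cytosol lists were short; without peaks that follow the list kind the measured counts were 5021 and 5063. The all-peak test called 29125 higher and 5960 lower, with 73.8% of calls at peaks that a whole group did not list, and its count of 35085 became 6068, 5965, 6125, 6983, 7139, 7051 and 6822 without A549 cytosol DMSO replicates 1 and 2, cytosol cisplatin replicate 2, polysome DMSO replicate 1, polysome cisplatin replicate 1, polysome DMSO replicate 2 and polysome cisplatin replicate 2.

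Lastly, the cisplatin response on polysomes was tested against that in cytosol. Over measured peaks edgeR called 0 differences, with 208 of 17308 peaks at an unadjusted p under 0.05, and DESeq2 called 0 with 202. That is again a smaller share than the 0.05 that would come without any difference. These fits did not use the pairing by number, so 0 calls do not show equal responses. The peak at 36653514 on chromosome 6 had a log2 change of 3.84 ± 0.35 on polysomes and 3.54 ± 0.54 in cytosol, and that at 133750158 on chromosome 7 had -4.28 ± 0.34 and -3.37 ± 0.33, each from the fit of its own fraction. Over upstream pairs edgeR called 0, with 99 of 5527 at an unadjusted p under 0.05, also under the share that would come without any difference. The 95% interval of the difference, not adjusted for the number of peaks, reached a median of 1.01 to either side. Calls needed an adjusted p, so differences larger than that could go uncalled. The all-peak test called 1 (lower on polysomes, at a peak that a whole group did not list), DESeq2 111, and without a count minimum edgeR called 196. The count of 1 became 3, 2 and 3 without A549 cytosol cisplatin replicate 2, polysome cisplatin replicate 1 and polysome DMSO replicate 3, and 0 without any of A549 cytosol DMSO replicates 1, 2 and 3, cytosol cisplatin replicates 1 and 3, and polysome DMSO replicates 1 and 2 and polysome cisplatin replicate 2.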

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

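All tests of explanations below, of other splits and of relabelled libraries were chosen after the result they bear on was seen, as were the tests of response differences over measured peaks; those over all peaks were planned.

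The cisplatin responses of A549R and A549 cytosol were called different at 7 peaks, and those of A549 polysomes and cytosol at 1, by a test of the difference itself over all peaks, which is why they are singled out. All 7 and the 1 lay at peaks that a whole group did not list. Over measured peaks 0 were called by edgeR and 0 by DESeq2. At an unadjusted p under 0.05 edgeR had 307 of 16439 and 208 of 17308, a smaller share than would come without any difference. Of 100 groupings in which libraries were relabelled at random, the real one included, 1 gave a count as large as 7 (highest other 5). This does not exclude chance for that count, because the 7 peaks lack listed values in a whole group and relabelling breaks up those groups. For the count of 1, 22 of 100 groupings did, so chance was not excluded, and the highest other count was 26601. Over measured peaks the real counts were 0, which all 100 groupings reach by construction. Other groupings gave up to 425 for A549R against A549 and 163 for polysomes against cytosol. Relabelling can move differences between lines or fractions, treatments and list kinds into the tested contrast. These groupings therefore decide nothing about the response differences.

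The unlisted class rose in H358 with cisplatin, from 18.1 ± 0.40% to 29.5 ± 3.36% of counts (n = 3). Fitted with all peaks listed in every DMSO and cisplatin library, 4134 of its 12306 peaks rose and 210 fell (median log2 0.71), whereas 909 of 15328 kept-class peaks rose and 4796 fell (median -0.48). Library depth did not explain it, since after thinning to a common total the lowest cisplatin share still exceeded the highest DMSO share by 7.81 percentage points. Whether the ends lie inside transcripts that end at a kept-class peak downstream stayed open. The median change was 0.65 for the 1389 peaks with such a peak within 50 kb and 0.72 for the 10889 without. Changes above 0 made up 78.0% and 87.4%. The gap in medians lay inside the spread of single peaks (median absolute deviation 0.43 and 0.36). That spread does not measure how well a median is known, so it decides nothing. A shift common to the class stayed open too. Scaled on its own, the class had 431 rises and 748 falls and the kept class 1905 and 1935, but that scaling centres each class by construction and decides nothing. Merged peaks in every long and no short list had a median width of 74 bases, against 430 for those in all libraries. What else sets the class apart was not tested, and a filter on internal priming was not run.

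Whole regions differed between A549R and A549, in 28 windows in DMSO and 28 in cisplatin, of which 25 were shared. With the correlation estimated these were 8 and 11, of which 8 were shared. The kind of peak list did not explain them: between long and short polysome lists the windows higher in A549R shifted by -0.0118 ± 0.18 on the log2 scale, against 0.39 between the lines. The means per library showed no single deviating library, as the lowest of the 6 A549R libraries had a mean of 0.27 in those windows and the highest A549 library 0.04. Those windows were picked from the same libraries, so part of this gap is built in. Other splits of the 6 DMSO libraries gave up to 26 windows, and in cisplatin, fitted alone, up to 27 against the real 29; each of these splits still sets 2 libraries of a line against 1, and camera at a preset correlation does not use the spread between libraries. A difference in copy number between the lines is consistent with blocks of this kind on chromosomes 22, 19 and 7 and stays a hypothesis, since no DNA was analysed here.

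Upstream peaks were lower on polysomes than in cytosol in A549, by -0.18 on the log2 scale in the median over upstream pairs (n = 6, exact permutation p 0.00216; exact sign flips over 6 pairs p 0.0312, adjusted 0.438, which did not pass). Oxaliplatin differed from DMSO in H358 by as much, without passing. The kind of peak list did not explain this, because the highest polysome library with a short list still lay -0.12 from the lowest cytosol library, whose list is also short. That any weaker peak of a pair is lower on polysomes did not either, as the difference was -0.0019 over pairs with the weaker peak downstream. That transcripts with upstream ends are less often on heavy polysomes is a hypothesis drawn from this difference, and no test apart from it was made. By their identifiers the fractions came from separate library sets, and a difference between library sets other than the list kind was not tested.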

How the results depend on the processing

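All values for measured peaks, upstream pairs and windows, and the settings kept class, 2 groups alone, 20 kb, kept-class pairs, left-out libraries numbered 3 and estimated correlation, were chosen after the data had been seen; the other settings of the all-peak counts were planned. Of 158 settings of 29 counts, besides omitted libraries, 96 stayed within 1.5 times the main count and 62 moved further. Of 2072 settings of 155 named values, 1859 kept direction and side of the threshold, 209 kept the direction but not the threshold, and 4 reversed. The cause was not tested for the moved counts below, except where fewer peaks or libraries entered by construction.

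Without a count minimum, all-peak counts were 14402 for H358 cisplatin, 3441 for A549 cisplatin, 3357 for A549R cisplatin, 42783 for A549R against A549, 1060 for the A549R minus A549 response, 1 for polysome cisplatin and 196 for the polysome minus cytosol response. With DESeq2 they were 16047 for H358 cisplatin, 2470 for A549 cisplatin, 1937 for A549R cisplatin, 125 for the A549R minus A549 response, 375 for polysome cisplatin and 111 for the polysome minus cytosol response. With DESeq2, measured counts were 1327 for oxaliplatin, 2172 for A549 cisplatin, 1713 for A549R cisplatin, 958 for A549R against A549 and 1562 for polysome cisplatin. Over the kept class, all-peak counts were 5433 for H358 cisplatin, 762 for oxaliplatin, 5005 for cisplatin against oxaliplatin, 1323 for A549R against A549, 1 for polysome cisplatin and 12439 for polysomes against cytosol.

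With libraries thinned to the smallest total, all-peak counts were 12816 for oxaliplatin, 15062 for A549R against A549, 20379 for polysomes against cytosol and 0 for the polysome minus cytosol response; measured counts were 408 for oxaliplatin, 624 for A549 cisplatin, 387 for A549R cisplatin, 212 for A549R against A549 and 35 for polysome cisplatin, so depth limits these counts. With the replicate block, all-peak counts were 144 for A549 cisplatin, 79 for A549R cisplatin and 0 for the polysome minus cytosol response; measured counts were 2236 for oxaliplatin, 4221 for cisplatin against oxaliplatin, 1959 for A549 cisplatin, 1552 for A549R cisplatin, 916 for A549R against A549 and 2031 for polysome cisplatin; pair counts were 361 for oxaliplatin, 54 for A549R against A549 and 229 for polysome cisplatin. With peaks within 100 bases merged, the polysome minus cytosol response had 0, and without the polysome libraries numbered 3 it had 8. Over a peak set drawn anew from those listed in every library of the 2 groups alone, measured counts were 10049 for H358 cisplatin, 400 for A549R cisplatin and 224 for A549R against A549.

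With partners within 20 kb, pair counts were 310 for H358 cisplatin, 97 for oxaliplatin, 63 for A549 cisplatin, 32 for A549R cisplatin, 3 for polysome cisplatin and 844 for polysomes against cytosol, where fewer pairs were tested. Over kept-class pairs, listed or not, they were 14 for A549 cisplatin, 0 for A549R cisplatin, 448 for A549R against A549 and 0 for polysome cisplatin. With the correlation estimated, 8 windows passed in DMSO and 11 in cisplatin. The 4 reversals came from another neighbour within 20 kb: in H358 cisplatin the peaks 19:49376862-49378078+ (3.78 to -0.0586) and 8:32870759-32871126+ (4.01 to -0.80), in A549R cisplatin 1:900809-901109+ (-3.04 to 0.22), and in polysome cisplatin 1:910995-911269+ (-3.52 to 0.36).

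Leave-one-out ranges of the all-peak counts were 5559 to 11826 for H358 cisplatin, 15734 to 23250 for oxaliplatin, 20813 to 23459 for cisplatin against oxaliplatin, 49 to 517 for A549 cisplatin, 16 to 405 for A549R cisplatin, 23764 to 28798 for A549R against A549, 6 to 24 for the A549R minus A549 response, 0 to 0 for polysome cisplatin, 5965 to 37483 for polysomes against cytosol and 0 to 3 for the polysome minus cytosol response. In the same order the measured counts were 2642 to 3977, 323 to 1060, 1851 to 2996, 407 to 1488, 193 to 1243, 130 to 534, 0 to 1, 11 to 120, 9228 to 10520 and 0 to 0. Pair counts were 397 to 637 for H358 cisplatin, 69 to 196 for oxaliplatin, 34 to 174 for A549 cisplatin, 15 to 133 for A549R cisplatin, 9 to 38 for A549R against A549, 0 to 10 for polysome cisplatin and 1330 to 1598 for polysomes against cytosol. Windows were 21 to 33 in DMSO and 26 to 33 in cisplatin. A group left with a pair of libraries was assumed to vary like the others of its fit.

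Not run, as they need an annotation or genome of the build, were the tests of intronic sites against last exons and their alternatives (any upstream peak, all peaks of the gene, last exons without extension, a filter on internal priming), the tests of 26 gene lists, the share of intronic sites and the tests by gene length; a pseudocount of 5 CPM and an adjusted p under 0.01 were set for those tests and not run either.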

Other observations

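The overlaps and the splits below were chosen after the comparisons were seen, the splits as tests of single results. Cisplatin moved many of the same transcript ends in separate lines and fractions. Of the measured peaks tested in both, 123 rose in H358 and in A549 cytosol where 46.0 would be shared by independent sets, and 213 fell in both where 47.6 would be, while 4 rose and 19 fell in H358 and moved the other way in A549. Between A549 and A549R cytosol 258 rises (13.2 expected) and 238 falls (13.6 expected) were shared, and between A549 cytosol and polysomes 72 rises (2.47 expected) and 34 falls (1.55 expected), each with 0 opposite. Same-numbered libraries deviated together between polysomes and cytosol (0.206 to 0.597 in cisplatin). Between A549R and A549 they did so in DMSO (0.125 to 0.24) and less evenly in cisplatin (-0.01 to 0.212). These sets therefore need not be independent. H358 shared 90 rises and 109 falls with A549R cytosol (33.8 and 26.1 expected), with 4 and 23 opposite, and 17 and 14 with polysomes (6.07 and 2.59 expected), with 1 and 6 opposite. Over all peaks tested in both, log2 changes correlated at 0.47 between H358 and A549 cytosol, 0.40 between H358 and A549R, 0.76 between A549R and A549 and 0.82 between A549 cytosol and polysomes (Pearson), each with controls of its own. The cisplatin changes also correlated with a contrast without treatment, long minus short polysome lists (Spearman -0.24 for H358, -0.29 for A549, -0.24 for A549R and -0.29 for polysomes), so part of the overlap need not come from treatment; how large a part was not tested.

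Single peaks show both sides of this. The peak at 36653514 on chromosome 6 rose in H358 (log2 2.21 ± 0.26), A549 cytosol (3.54 ± 0.54), A549R cytosol (3.16 ± 0.53) and polysomes (3.84 ± 0.35), and that at 133750158 on chromosome 7 fell in each (-2.48 ± 0.43, -3.37 ± 0.33, -3.09 ± 0.35 and -4.28 ± 0.34). The peak at 76468066 to 76469065 on chromosome 10, plus strand, fell by 3.03, 3.05, 2.43 and 2.54. The peak at 69236866 to 69238124 on chromosome 12, plus strand, rose in A549 cytosol (2.76 ± 0.31), A549R cytosol (2.60 ± 0.31) and polysomes (3.74 ± 0.32), with -0.07 ± 0.35 in H358, and that at 949363 on chromosome 1 had 3.50 ± 0.60, 2.71 ± 0.58 and 3.80 ± 0.63 with -0.22 ± 0.21 in H358; the difference from H358, whose RNA was of whole cells, was not tested. The peak at 105945928 on chromosome 14 rose in A549R (3.24 ± 0.78) and A549 (2.80 ± 0.75) and fell in H358 (-1.09 ± 0.26). Over the 3 lines together the mitochondrial share was 1.52-fold higher with cisplatin (n = 9 per treatment, permutation within lines p 0.0065, adjusted 0.0357; with A549 and A549R pairs flipped, exact p 0.00313, adjusted 0.0344). H358 carried most of this rise, with 2.41-fold against 1.17-fold in A549 (exact permutation p 0.4) and 1.22-fold in A549R (exact p 0.3).

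Among windows of 5 Mb, camera passed 0 for cisplatin in H358, A549 cytosol, A549R cytosol and polysomes (5, 7, 8 and 9 at an unadjusted p under 0.05; with the correlation estimated, 0 passed) and 0 of 116 between polysomes and cytosol (7 unadjusted). For oxaliplatin 3 of 98 passed, 1 higher and 2 lower, and 0 with the correlation estimated.

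With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, so only the real count, with the 2 groups fitted alone over the same peaks as in the main fit, and the highest other are given; in each but polysome cisplatin over all peaks, 1 split, the real one, reached the real count. Over measured peaks these were 3617 and 1 for H358 cisplatin, 653 and 0 for oxaliplatin, 3066 and 0 for cisplatin against oxaliplatin, 959 and 1 for A549 cisplatin, 571 and 1 for A549R cisplatin, 201 and 2 for A549R against A549, and 152 and 2 for polysome cisplatin. Over upstream pairs they were 479 and 0 for H358 cisplatin, 148 and 0 for oxaliplatin, 124 and 1 for A549 cisplatin, 58 and 0 for A549R cisplatin, 11 and 2 for A549R against A549, and 17 and 3 for polysome cisplatin. Over all peaks they were 6169 and 0, 14997 and 0, 19507 and 0, 131 and 11, 4 and 1, 25467 and 0 and, for polysome cisplatin, 0 and 0, which all 10 splits reached. Where replicate numbers pair the libraries, 3 of the 9 other splits part each pair as the real one does, and the rest keep a pair on a side.

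Between polysomes and cytosol, 100 groupings were drawn. The measured count (10135, highest other 2) and the pair count (1588, highest other 1) were each reached by 1 grouping, the real one. These groupings ignore the pairing by number, so chance was not excluded for the paired design. The all-peak count of 35085 was reached by the real one alone too, but another grouping called 25423. Relabelling can set long against short lists, so such a count is no measure of chance.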
